A study of Mus musculus with 12 samples.

How the data were processed

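RNA from gastrocnemius and soleus of 4-week-old male C57BL/6 mice was sequenced in 12 libraries, 3 for each muscle and genotype. Per the labels' protocols, muscles were flash frozen, RNA was isolated with RNAiso and NucleoSpin columns, and directional libraries were made with a NEBNext Ultra II kit. Control mice were Phf2 flox/flox without Acta1-Cre and KO mice carried Cre, per the labels. The labels do not say that the 3 samples of a group come from separate mice, so p-values measure only the spread between these samples, nor whether muscles of the same number come from the same mouse.

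The deposited values are TPM made by the authors, in a table for each muscle with a column for each library, and every column sums to 1000000. The genome build was mm10 per the submitters' processing notes. The aligner, the quantifier and the annotation release are not given in the sources used here. TPM keeps no depth, so the depth per library and the precision of low values are unknown. Genes above 0 numbered 18291 to 20175 per library and genes at 1 TPM or more 11764 to 12157. The largest share of values above 0 that was identical between any pair of libraries was 0.00287%.

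Each table holds 34866 gene IDs. Without their version numbers, 34582 were matched to symbols, biotypes and coordinates of GENCODE mouse release M21, and 284 were not. 26 symbols were held by more than 1 ID.

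Values were transformed to log2(TPM + 1). Fold changes on this scale understate changes of genes with low TPM. In each muscle, genes with a mean of at least 1 TPM over its 6 libraries were fitted with limma 3.58.1 (R 4.3.3, version 1.17.8 of data.table), with KO and Ctrl group means, a mean-variance trend in the empirical Bayes prior and two-sided moderated tests. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p under 0.05 without a fold threshold. Phf2 was also tested with an exact permutation test, whose smallest p is 0.1 with 3 against 3 libraries.

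Gene groups were 37 lists of genes fixed beforehand. Lists with at least 5 measured members were tested with camera in limma at a preset correlation of 0.01, with adjustment over the lists. For each list the number of members called over all genes and the number called when adjusted over the list alone are given. The difference between muscles was the soleus KO effect minus the gastrocnemius KO effect in a limma fit of all 12 libraries with 4 group means, over genes with a mean of at least 1 TPM in them. Overlap of calls was tested per direction with Fisher's exact test, two-sided, over genes tested in both muscles, beside the number independent lists give, the product of the list sizes over the number of genes.

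The groups, tests, gene lists, the rule for named genes and the first set of alternatives were chosen before the data were examined. The rule names Phf2, then per muscle the 10 largest rises and 10 largest falls among called genes whose groups do not overlap. Predicted genes, Riken clones, pseudogenes and further members of near-identical families are passed over. In a muscle with fewer than 10 called genes, the 10 genes of smallest p are named. Up to 4 members of smallest p are named per list, together with Myh7, Myh2, Myh1 and Myh4, up to 5 genes per direction for the difference between muscles, and up to 10 called in both.

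Alternatives were pseudocounts of 0.1 and 0.5, no filter or a filter at a mean of 5 TPM, median-ratio scaling, quantile normalization, rescaling without mitochondrially encoded genes, robust empirical Bayes, array weights, no trend, the replicate number as a block, a fit of all libraries together, and leaving out each library in turn. For lists, camera with an estimated correlation and fry were further alternatives. Chosen after seeing the data were a lowess correction for GC content and transcript length (span 0.3), rescaling over protein-coding nuclear genes, the number of processed pseudogenes as a covariate, the presence of Gm12338 as a term in soleus, and soleus p-values adjusted over the gastrocnemius calls. Genotype labels were exchanged in all 10 splits of 3 against 3 per muscle, and in 100 of 200 possible splits over both muscles.

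The pipeline was tested on simulated data with 200 changed genes. At 1.5-fold, 2-fold and 4-fold, 67.2%, 85.1% and 100% of them were recovered in gastrocnemius and 23.9%, 59.7% and 92.4% in soleus. For the difference between muscles 23.9%, 62.7% and 95.5% were recovered. Unchanged genes made up 4.66%, 3.28% and 7.41% of the genes called. The simulated noise was independent between genes and held no difference shared by a library, and the changed genes lay above a higher expression floor. These rates therefore do not give the error rate of the real calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No sample or column was left out.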

Results

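RNA was sequenced from gastrocnemius, a mixed and mostly fast-twitch calf muscle, and from soleus, a slow-twitch postural muscle, of 4-week-old male C57BL/6 mice. Knockout (KO) mice carried floxed Phf2 alleles and an Acta1-Cre transgene, which is active in skeletal muscle fibres, and control (Ctrl) mice carried the floxed alleles without Cre. PHF2 is a plant homeodomain protein of the Jumonji family that acts on lysine methylation of histones and other proteins. The 12 libraries formed 4 groups of 3, and the stated purpose was to examine the role of PHF2 in skeletal muscle. Expression was given as TPM, transcripts scaled to the same sum in each library, which keeps no read depth, so the depth behind each value is unknown. Values are the mean ± SD of n = 3 libraries per group, and log2 fold changes (KO minus Ctrl) are on the log2(TPM + 1) scale with their SE.

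The libraries differed in ways that followed genotype in gastrocnemius. Genes of all kinds above 0 TPM numbered 18466, 18291 and 18699 in gastrocnemius Ctrl 1 to 3 and 19731, 20175 and 19676 in KO 1 to 3. In soleus they numbered 19802, 18453 and 19658 in Ctrl 1 to 3 and 19463, 19989 and 19480 in KO 1 to 3. Processed pseudogenes, reverse-transcribed copies of mRNAs, were listed above 0 TPM in 1098 ± 72.7 cases in gastrocnemius Ctrl and 1652 ± 122 in KO, against 1457 ± 345 in soleus Ctrl and 1513 ± 240 in soleus KO. The pseudogene Gm12338, singled out after its values were seen, was listed at 0 in all 3 gastrocnemius Ctrl libraries and between 99.4 and 194 TPM in the 3 KO libraries. In soleus it was at 0 in Ctrl 2, KO 1 and KO 3 and above 0 in the other 3, so that only soleus held both kinds of library within a genotype. For a gene or gene group, "library shift" below means the soleus difference between libraries with and without Gm12338 within genotype. It sets Ctrl 1 and Ctrl 3 against Ctrl 2, and KO 2 against KO 1 and KO 3. Each genotype thus has 1 library on one side, and KO 3, which differed most from the other soleus libraries, enters every library shift. Mitochondrially encoded transcripts made up 23.3 ± 1.11% of TPM in gastrocnemius Ctrl and 19.7 ± 1.39% in KO. In soleus the shares were 27.1 ± 2.55% in Ctrl and 31.1 ± 6.93% in KO, with KO 3 at 39.0%. The slope on GC content (as a fraction, beside transcript length) of each library's log2 deviation from the mean of its muscle was -1.16, -0.48 and -0.53 in gastrocnemius Ctrl 1 to 3 and 1.01, 0.50 and 0.66 in KO 1 to 3. In soleus it was between 0.20 and 0.92 in 5 libraries and -2.56 in KO 3.

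**Figure D1:**
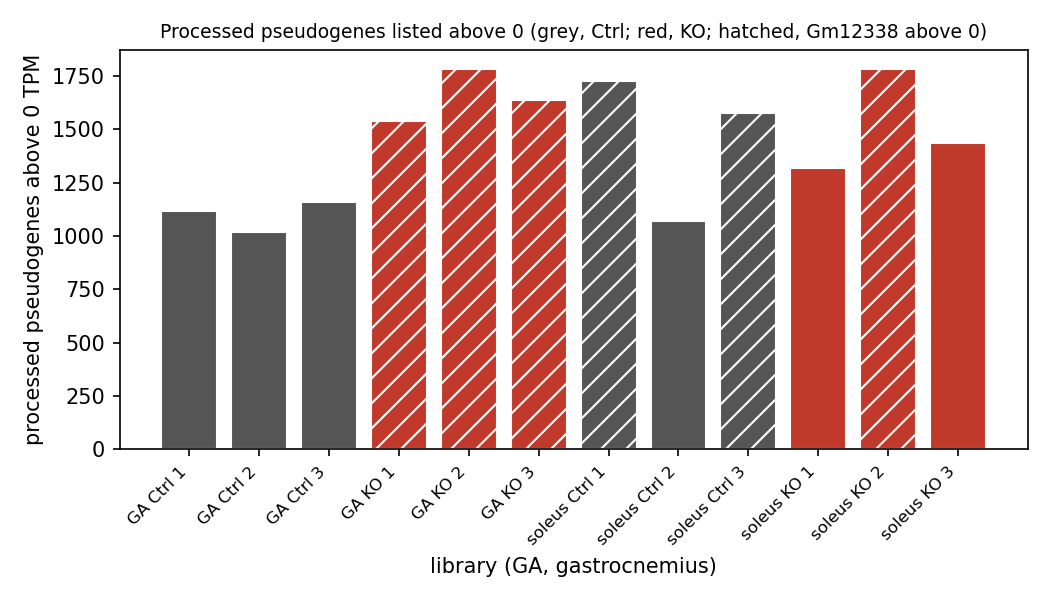
Number of processed pseudogenes listed above 0 TPM (vertical axis) in each of the 12 libraries, grey for Ctrl, red for KO and hatched where Gm12338 was above 0. The gastrocnemius Ctrl libraries lie between 1018 and 1160 and the gastrocnemius KO libraries between 1539 and 1781, whereas the soleus groups overlap.

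Phf2 itself, on chromosome 13 from 48801750 to 48871119 (minus strand, mm10), was at 9.87 ± 1.57 TPM in gastrocnemius Ctrl and 7.12 ± 0.445 TPM in KO, or 72.1% of Ctrl. In soleus it was at 13.0 ± 2.64 TPM in Ctrl and 7.99 ± 1.14 TPM in KO, or 61.4%. In both muscles each KO library lay below each Ctrl library, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. The log2 fold change was -0.41 (SE 0.118, adjusted p = 0.0601 by limma) in gastrocnemius and -0.63 (SE 0.174, adjusted p = 0.326) in soleus. The labels do not say which exons are floxed, and gene-level TPM also counts RNA from cells other than muscle fibres and any RNA left from a recombined allele. 

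**Figure D2:**
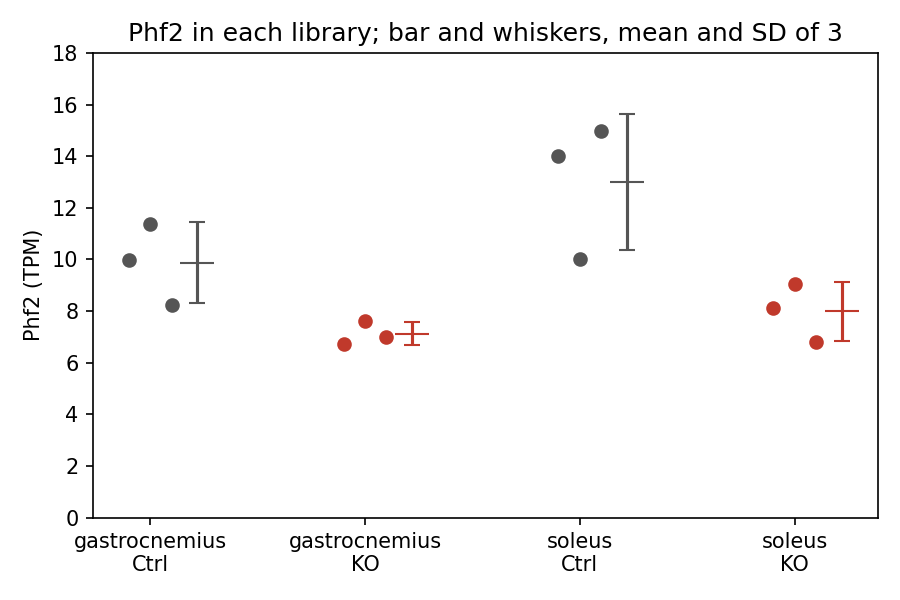
Phf2 in TPM (vertical axis) in each library of the 4 groups, with the mean and SD of 3 libraries beside the points. In gastrocnemius the KO libraries lie between 6.74 and 7.61 TPM and the Ctrl libraries between 8.24 and 11.4 TPM, and in soleus KO lies between 6.79 and 9.06 TPM and Ctrl between 10.002 and 15.0 TPM.

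In gastrocnemius, the knockout was compared with control to ask which genes change when Phf2 is deleted in fibres of a mostly fast muscle. Of 11911 genes tested with limma, 1110 were higher and 594 lower in KO, with 102 and 44 of them changed more than 2-fold. Cdkn1a, the cell-cycle inhibitor p21 induced by p53, rose from 10.3 ± 1.22 to 40.5 ± 11.4 TPM (log2 fold change 1.85, SE 0.190, adjusted p = 0.00428). Dmd, which encodes dystrophin of the sarcolemma, fell from 28.8 ± 0.450 to 10.9 ± 1.63 TPM (-1.33, SE 0.108, adjusted p = 0.00249). Cytosolic ribosomal protein genes, embryonic and developmental muscle genes and p53 target genes were higher as groups, and mitochondrially encoded transcripts were lower by camera (adjusted p = 0.990 for each with an estimated correlation). In each of the 1704 called genes all 3 KO libraries lay on the same side of all 3 Ctrl libraries. That held for 37.7% of all tested genes, where chance gives 10%.

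Among the largest rises, Chrna9, a nicotinic acetylcholine receptor subunit, rose from 0.497 ± 0.147 to 5.47 ± 0.908 TPM (log2 fold change 2.11, SE 0.137, adjusted p = 0.00106). Sln, the sarcolipin that inhibits the sarcoplasmic calcium pump, rose from 5.39 ± 1.94 to 22.5 ± 8.38 TPM. Rrad, a small GTPase that restrains voltage-gated calcium channels, rose from 2.09 ± 0.352 to 17.998 ± 11.8 TPM, and Atp1b4, a muscle protein of the sodium pump beta-subunit family, from 4.20 ± 1.01 to 17.5 ± 5.77 TPM. Ppp1r1a, an inhibitor of protein phosphatase, had the smallest p of the named rises, with 30.1 ± 2.64 TPM in Ctrl and 99.0 ± 3.14 TPM in KO (1.69, SE 0.0791, adjusted p = 0.000297). Mt3, a metallothionein, rose by 2.50 (SE 0.463) and Cpne2, a calcium-dependent membrane-binding copine, by 1.86 (SE 0.148) on the log2 scale. Rps27, a small ribosomal subunit protein with near-identical copies elsewhere in the genome, rose by 2.50 (SE 0.174) and the mitochondrial mt-Atp8 by 1.74 (SE 0.264), with library shifts of 0.83 and 1.25.

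Among the largest falls, Cntnap2, a neurexin-family adhesion protein, fell from 10.6 ± 0.375 to 2.66 ± 0.404 TPM (log2 fold change -1.67, SE 0.102, adjusted p = 0.000856). Sall4, a zinc-finger transcription factor, fell from 9.87 ± 1.34 to 2.69 ± 0.510 TPM. Rps6ka2, a ribosomal S6 kinase downstream of ERK, fell from 35.4 ± 5.18 to 13.4 ± 2.28 TPM, and Asb14, a substrate adaptor of ubiquitin ligases, from 94.5 ± 5.51 to 37.7 ± 6.50 TPM. Mss51, a mitochondrial protein of skeletal muscle, fell by 1.42 (SE 0.301) on the log2 scale, Htra4, a serine protease, fell from 5.48 ± 1.87 to 1.54 ± 0.952 TPM, and Cd28, a T-cell costimulatory receptor, from 2.88 ± 0.654 to 0.590 ± 0.0142 TPM. Epb41l5, a FERM-domain protein of cell polarity, had the largest fall (-2.42, SE 0.226) and a library shift of -2.09, so that soleus libraries of the same genotype differed by nearly as much. Rsc1a1, a regulator of glucose transport, fell by 1.54 (SE 0.305) with a library shift of -1.03. Of these 20 genes, 15 remained called when each library was left out in turn, and Mt3, Rrad, Rsc1a1, Mss51 and Htra4 did not. In every other setting but the pseudogene covariate 13 of the 20 remained called, and of all 122 called genes chosen for naming in gastrocnemius, 56 remained called without each library.

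Among the 75 measured cytosolic ribosomal protein genes, 27 rose, 1 fell and 47 did not pass, with a median log2 fold change of 0.27 (camera adjusted p = 6.0e-09; adjusted p = 0.990 with an estimated correlation). The count adjusted over the list alone was 36 up and 2 down. Rpl13a rose from 481 ± 54.2 to 847 ± 25.2 TPM, Rps28 from 454 ± 33.0 to 729.8 ± 42.0 TPM and Rpl35a from 352 ± 22.6 to 533 ± 15.5 TPM. Such genes have near-identical processed pseudogenes, and how reads were shared out among them is unknown here, so each single value is uncertain. The list's library shift was 0.01. It was called by camera in each of 21 alternative settings of the fit and not by fry (adjusted p = 0.153).

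Of 18 measured developmental myogenic genes, which are expressed in embryonic, neonatal and regenerating muscle, 9 rose, 0 fell and 9 did not pass (median 0.46; camera adjusted p = 7.50e-04; adjusted p = 0.990 with an estimated correlation). Adjusted over the list alone, 11 rose. Myh8, the perinatal myosin heavy chain, rose from 1.36 ± 0.139 to 5.92 ± 1.79 TPM, Tnnt2, the cardiac and embryonic troponin T, from 7.70 ± 0.988 to 18.8 ± 6.69 TPM, and Igf2, a fetal growth factor, from 45.1 ± 9.70 to 97.4 ± 24.1 TPM. Ankrd1, a stretch-responsive titin-binding repeat protein, rose from 6.45 ± 1.70 to 17.7 ± 5.41 TPM. The list's library shift was 0.03, and it was called in each of 21 alternative settings.

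Of 16 measured p53 target genes, 8 rose, 0 fell and 8 did not pass (median 0.35; camera adjusted p = 0.0125; adjusted p = 0.990 with an estimated correlation). There were 9 rises when adjusted over the list alone. Besides Cdkn1a, the nuclease gene Aen rose from 20.9 ± 0.987 to 33.6 ± 2.04 TPM, Bax, which permeabilises the outer mitochondrial membrane, from 20.0 ± 1.09 to 33.7 ± 3.23 TPM, and Ei24 from 46.1 ± 0.914 to 58.0 ± 1.22 TPM. The list's library shift was -0.03, and it was called in each of 21 alternative settings.

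Of 19 measured neuromuscular junction genes, 2 rose, 1 fell and 16 did not pass (median 0.26; camera adjusted p = 0.0223; adjusted p = 0.990 with an estimated correlation). Adjusted over the list alone, 9 rose and 1 fell. The acetylcholine receptor subunits Chrna1 and Chrne rose by 0.65 (SE 0.156) and 0.29 (SE 0.0688), and Musk, the receptor kinase that clusters them, fell by 0.55 (SE 0.136). Chrna1 lost its call in 5 of 6 fits that left out a library, and Chrne and Musk in 6 of 6. The list was called in 17 of 21 alternative settings, and the call was lost with a filter at 5 TPM, in a fit of all libraries, with GC and length correction and without gastrocnemius KO 2. By fry, a test of whether a list's genes move on balance to the same side, the p53, developmental and neuromuscular junction lists passed (adjusted p = 0.0161, 0.0464 and 0.0464). Other splits of the 6 libraries into 3 and 3 called between 5 and 11 lists by camera, where the genotype split called 5.

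Of 13 measured mitochondrially encoded genes, 1 rose, 4 fell and 8 did not pass (median -0.14; camera adjusted p = 0.0105; adjusted p = 0.990 with an estimated correlation). When adjusted over the list alone, 1 rose and 5 fell. mt-Nd3 fell from 19790.5 ± 924 to 9809 ± 413 TPM, mt-Co3 from 32742 ± 810.2 to 24096 ± 1002 TPM and mt-Atp6 from 30832 ± 1023 to 24518 ± 1223 TPM, while mt-Atp8, whose reading frame overlaps that of mt-Atp6, rose. Over the members, the gastrocnemius change and the library shift correlated at r = 0.972 across genes, which are not independent replicates. The list was not called by fry (adjusted p = 0.183) and was called by camera in 14 of 19 alternative settings, and the call was lost with no filter, with quantile normalization, in a fit of all libraries, with GC and length correction and without gastrocnemius KO 1.

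**Figure D3:**
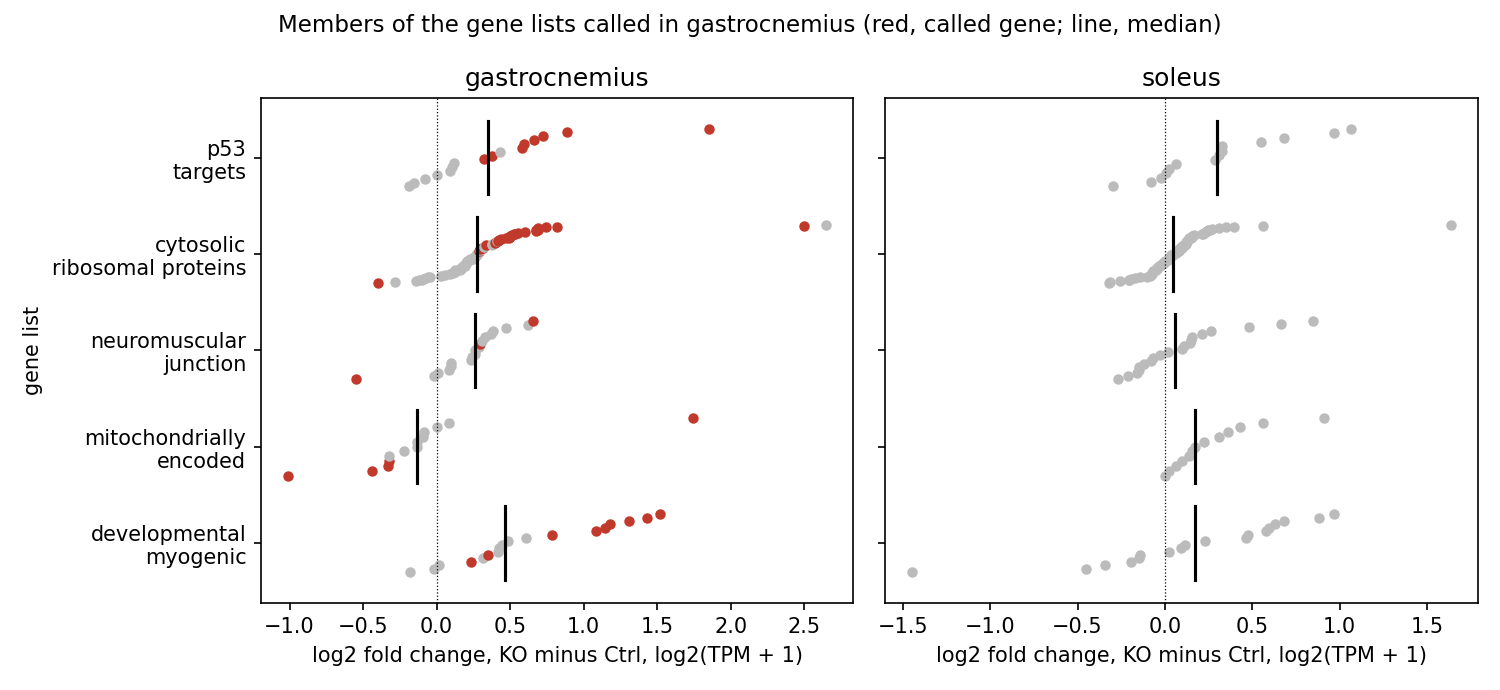
Log2 fold change (horizontal axis, KO minus Ctrl on log2(TPM + 1)) of each measured member of the 5 gene lists called in gastrocnemius, in gastrocnemius (left) and soleus (right), red where the gene passed the test and with a line at the median. The ribosomal median is 0.27 in gastrocnemius and 0.05 in soleus, and the median of the p53 targets is 0.35 (16 genes) and 0.30 (14 genes). Single p53 targets differed between the muscles. Bax and Ei24 were above 0 only in gastrocnemius, Ccng1 and Trp53inp1 only in soleus, and Cdkn1a and Aen in both.

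A further 18 lists held at least 2 called members without being called as lists, with camera adjusted p-values from 0.212 to 0.983. Of 48 nuclear-encoded oxidative phosphorylation genes, 8 rose and 9 fell, and adjusted over the list alone 10 rose and 10 fell. Cox6a2, the muscle form of a cytochrome oxidase subunit, rose from 1011 ± 127 to 1927 ± 72.4 TPM and the complex I subunit Ndufb10 from 384 ± 23.7 to 555 ± 38.9 TPM, whereas the complex I subunit Ndufb5 fell from 516 ± 18.8 to 396 ± 22.3 TPM. These members' changes correlated with their library shifts at r = 0.741 across genes. Of 25 glycolysis and glycogen genes, 2 rose and 4 fell (5 and 6 adjusted over the list alone). Ugp2, which makes UDP-glucose for glycogen, fell from 342 ± 13.0 to 216 ± 7.28 TPM. Of 28 fatty acid oxidation genes, 1 rose and 2 fell, also adjusted over the list alone, and Cd36, the fatty acid transporter, fell from 117 ± 11.8 to 76.2 ± 2.11 TPM. Of 16 tricarboxylic acid cycle genes, 1 rose and 1 fell (2 and 1 adjusted over the list alone), and of 25 lipid and sterol synthesis genes 4 rose and 2 fell, also adjusted over the list alone. The sterol regulator Srebf1 rose by 0.43 (SE 0.0787).

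Among contractile lists, 6 excitation-contraction and calcium genes rose and 2 fell of 25, also adjusted over the list alone. Casq2, the cardiac and slow-fibre calsequestrin, rose from 21.4 ± 3.69 to 67.5 ± 13.8 TPM, and Casq2 and Sln were also the only called members of the 16 slow fibre genes, over all genes and adjusted over the list alone. Of 18 fast fibre genes, 4 rose and 2 fell (4 and 3 adjusted over the list alone). Mylk4, a myosin light chain kinase family member, fell from 355 ± 64.8 to 156 ± 37.4 TPM. The fibre-type myosins did not pass. Myh4, of the fastest fibres, was at 10243 ± 601 and 11743 ± 429 TPM in Ctrl and KO, Myh1 at 729 ± 116 and 572 ± 128, Myh2 at 343 ± 42.7 and 394 ± 90.6, and the slow Myh7 at 59.5 ± 16.2 and 79.2 ± 52.5. Of 30 sarcomere and Z-disc genes, 4 rose and 3 fell (6 and 6 adjusted over the list alone), with Capn3, a muscle calpain, falling by 0.36 (SE 0.0578) and Ttn by 0.29 (SE 0.0545).

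Among growth and stress lists, 4 of 21 denervation and atrophy genes rose and 1 fell (6 and 3 adjusted over the list alone). Gadd45a, a stress gene raised in denervated muscle, rose from 42.6 ± 6.85 to 80.3 ± 10.6 TPM, and Mstn, the inhibitor of muscle growth myostatin, fell from 33.4 ± 4.74 to 17.8 ± 3.07 TPM. Of 26 growth signalling genes, 2 rose and 2 fell, also adjusted over the list alone, and the insulin-like growth factor binding protein Igfbp5 rose from 112 ± 3.67 to 196 ± 24.0 TPM. Of 18 NRF2 and oxidative stress genes, 2 rose and 2 fell, also adjusted over the list alone, with the metallothionein Mt2 rising from 25.4 ± 2.59 to 60.0 ± 10.1 TPM. Of 16 endoplasmic reticulum chaperone genes, 3 rose (3 up and 1 down adjusted over the list alone), led by Canx, calnexin, at 31.1 ± 1.18 and 53.4 ± 9.64 TPM. Canx had a library shift of 0.76, and over this list the change and the shift correlated at r = 0.818 across genes. Of 17 cytosolic heat shock genes 2 rose, also adjusted over the list alone. Of 27 proteasome genes 2 rose and 3 fell, also adjusted over the list alone, and of 20 autophagy and lysosome genes 2 rose (1 adjusted over the list alone).

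Among markers of other cell types, 2 of 20 fibroblast genes rose and 1 fell, also adjusted over the list alone. Mfap4, a microfibril protein, rose from 30.4 ± 5.99 to 67.8 ± 13.1 TPM, with a library shift of 0.84. Of 13 smooth muscle and pericyte markers 3 rose (4 up and 1 down adjusted over the list alone). The remaining 14 lists had at most 1 called member. It rose in 7 of them (integrated stress response, cell cycle, glucocorticoid and fasting, satellite cell, macrophage and immune, endothelial, and adipocyte) and fell in the circadian clock list. None was called in the immediate early, interferon, H3K9 methylation enzyme, tendon, erythroid, and Schwann cell and nerve lists. Adjusted over the list alone, no member passed in the satellite cell and macrophage lists and the other counts were the same. Adipocyte, tendon and macrophage markers had uncalled medians of 0.62, 0.56 and 0.36 in gastrocnemius and library shifts of 0.97, 0.84 and 0.54.

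In the proteasome, oxidative phosphorylation, fatty acid oxidation, glycolysis, lipid synthesis, sarcomere, growth signalling and immediate early lists, none of them called, the median, the mean and the camera direction differed in sign. The share of calls that were higher was 65.1% as deposited and 53.1% with median-ratio scaling, 48.5% after rescaling without mitochondrial genes, 45.8% with quantile normalization and 43.4% after rescaling over protein-coding nuclear genes, and 71.2% after GC and length correction, 69.3% with no filter and 68.0% with the replicate block. A joint fit of all libraries called 259 genes higher and 265 lower in gastrocnemius. With the number of processed pseudogenes added to that fit as a covariate, 1 gene was higher (Klhdc1) and 2 lower (Cntnap2 and Pde7a, the latter named after its value was seen), and 981 had an unadjusted p under 0.05. The covariate moved with genotype in this muscle and widened the SE 1.52 times at the median. Leaving out Ctrl 1, Ctrl 2, KO 1, KO 2 or KO 3 gave 398, 548, 716, 382 and 586 higher and 165, 233, 383, 165 and 235 lower genes.

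In soleus, the same comparison asked which genes change in a mostly slow muscle. Of 12148 genes tested with limma, 2 were higher and 7 lower in KO, with 1102 at an unadjusted p under 0.05. Tmx4, a thioredoxin-related membrane protein of the endoplasmic reticulum, rose from 8.55 ± 1.33 to 36.7 ± 6.02 TPM (log2 fold change 1.98, SE 0.159, adjusted p = 0.0248). Acsl6, an acyl-CoA synthetase that activates long-chain fatty acids, fell from 14.5 ± 0.852 to 4.71 ± 0.690 TPM (-1.45, SE 0.125, adjusted p = 0.0248). Fgf13, an intracellular partner of sodium channels, fell from 30.1 ± 0.333 to 13.5 ± 0.811 TPM (-1.10, SE 0.103, adjusted p = 0.0248), and Rps6ka2 from 36.4 ± 2.59 to 13.7 ± 2.93 TPM (-1.36, SE 0.157, adjusted p = 0.0482).

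The other called genes were at 10.4 TPM or below in both groups. Myocd, the smooth and cardiac muscle coactivator myocardin, rose from 0.158 ± 0.0861 to 2.30 ± 0.577 TPM (adjusted p = 0.0373). Hspa2, an HSP70 family chaperone, fell from 10.4 ± 1.53 to 2.92 ± 0.504 TPM (adjusted p = 0.0258). Cxcl11, a chemokine gene annotated as a polymorphic pseudogene, fell from 2.64 ± 0.370 to 0.519 ± 0.162 TPM, and the little-studied 4933415F23Rik and BC048679 fell to 0.459 ± 0.127 and 0.341 ± 0.136 TPM from 4.06 ± 0.888 and 3.24 ± 0.839. The next smallest p belonged to Tnfrsf23, a decoy death receptor, at 5.73 ± 0.135 and 17.4 ± 4.11 TPM, which did not pass (adjusted p = 0.0575). In all 9 called genes the KO and Ctrl libraries did not overlap, as in 16.8% of all tested genes, where chance gives 10%.

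Of the 37 lists, 13 were called in soleus with no member passing over all genes, and the adjusted p was 0.956 with an estimated correlation for each of them, while fry called 0 with adjusted p-values of 0.763 and above. The p53 targets had a median of 0.30 (camera adjusted p = 0.00190), and adjusted over the list alone 3 of 14 rose. The fatty acid oxidation genes had a median of -0.20 with 3 of 28 above 0 (camera adjusted p = 7.01e-04), and adjusted over the list alone none passed. Cdkn1a was at 22.4 ± 5.38 TPM in Ctrl and 47.7 ± 9.82 TPM in KO, Eda2r, a p53-induced death-domain receptor, at 5.20 ± 0.736 and 11.4 ± 3.21 TPM, and neither passed over all genes. Cd36 was at 300.0 ± 28.8 and 217 ± 22.0 TPM and Acot2, a mitochondrial thioesterase, at 29.2 ± 2.99 and 19.6 ± 3.06 TPM. Both lists were called in each of 22 alternative settings, and other splits of the 6 libraries called between 1 and 20 lists by camera.

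Lists called with medians below 0 also included endothelial markers (median -0.21, camera adjusted p = 0.00190), nuclear-encoded oxidative phosphorylation (-0.14, 0.0118), Schwann cell and nerve markers (-0.23, 0.0118) and the interferon response (-0.22, 0.0479). The endothelial receptor Tie1 was at 26.3 ± 3.10 and 20.0 ± 1.73 TPM and the Schwann cell regulator Sox10 at 1.96 ± 0.216 and 1.38 ± 0.211 TPM. Lists called with medians above 0 also included fibroblast markers (0.31, 0.00852), macrophage and immune markers (0.29, 0.0118), denervation and atrophy (0.23, 0.0427), mitochondrially encoded genes (0.17, 0.0427), cell cycle (0.13, 0.0427), developmental myogenic genes (0.17, 0.0477) and endoplasmic reticulum chaperones (0.13, 0.0477). The fibroblast proteoglycan Lum was at 21.1 ± 7.96 and 36.5 ± 2.74 TPM, the macrophage receptor Mrc1 at 4.30 ± 1.62 and 6.28 ± 0.405 TPM and Chrna1 at 10.5 ± 1.08 and 17.2 ± 1.96 TPM. Adjusted over the list alone, 3 denervation genes rose and no member of the other 10 of these lists passed. Library shifts were 0.58 for the fibroblast and 0.54 for the macrophage markers, and both calls were lost without soleus Ctrl 2, KO 2 or KO 3. Among soleus libraries with Gm12338 at 0 and above 0, the median was -0.31 and 0.06 for the Schwann cell markers and 0.06 and -0.39 for the interferon response. Of the alternative settings, calls were kept in 21 of 22 for endothelial, 18 for oxidative phosphorylation and for fibroblast, 17 for Schwann cell, 16 for macrophage, 15 for denervation, 14 for developmental, 13 for cell cycle, 12 for chaperone and 10 for interferon genes, and in 10 of 20 for mitochondrially encoded genes, whose call was lost without Ctrl 2, Ctrl 3 or KO 3.

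Among developmental genes, Myod1 was at 6.59 ± 3.16 and 13.1 ± 1.31 TPM, while Myh8 was at 15.4 ± 10.6 and 4.50 ± 2.09 TPM in Ctrl and KO. The slow Myh7 was at 4881 ± 599.9 and 3856 ± 1969 TPM, Myh2 at 2683 ± 281 and 2385 ± 283, Myh1 at 1492 ± 505 and 1008 ± 249.8, and Myh4 at 50.9 ± 24.4 and 146 ± 116. The remaining 24 lists were not called, with camera adjusted p-values from 0.0804 for the ribosomal proteins to 0.992 for the glucocorticoid and fasting list. None of their members passed over all genes, and adjusted over the list alone 1 neuromuscular junction gene rose, 1 glycolysis and 1 adipocyte gene fell, and 1 satellite cell gene rose and 1 fell. Median, mean and camera direction differed in sign for growth signalling, heat shock, glucocorticoid and tendon lists. Without soleus Ctrl 1, Ctrl 2 or KO 3, or with the presence of Gm12338 as a term, limma called 0 genes (744, 887, 1085 and 1080 at an unadjusted p under 0.05). Without Ctrl 3 or KO 1 it called 1 gene each, and without KO 2 it called 11, 6 higher and 5 lower.

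Between muscles, the overlap of calls asked whether Phf2 deletion changes the same genes in both. Rps6ka2, Acsl6 and Fgf13 fell and Tmx4 rose in gastrocnemius as well as in soleus. In gastrocnemius Acsl6 fell from 29.5 ± 3.20 to 16.6 ± 1.04 TPM, Fgf13 from 34.3 ± 2.96 to 14.9 ± 2.99 TPM, and Tmx4 rose from 7.50 ± 1.1996 to 17.98 ± 6.02 TPM. The genes lie on chromosome 17 from 7170115 to 7303315 (Rps6ka2), chromosome 11 from 54303798 to 54364756 (Acsl6), chromosome X from 59062145 to 59568071 (Fgf13) and chromosome 2 from 134594185 to 134644145 (Tmx4), all in mm10. Over 11635 genes tested in both, 3 were lower in both where independent lists of these sizes give 0.245 (Fisher's exact test, two-sided p = 0.00109), and 1 was higher in both where they give 0.0930 (p = 0.0930). Genes are not independent replicates, so these p-values do not measure the spread between samples. The number called in both was 0 without soleus Ctrl 1, Ctrl 2, Ctrl 3, KO 1 or KO 3, and 9 without KO 2. Over the 1652 gastrocnemius calls tested in soleus, the slope of the soleus change on the gastrocnemius change was 0.0917, and 40.9% had the same sign, against 45.7% of all genes. Among those with an unadjusted soleus p under 0.05, 164 had the same sign and 36 the opposite.

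**Figure D4:**
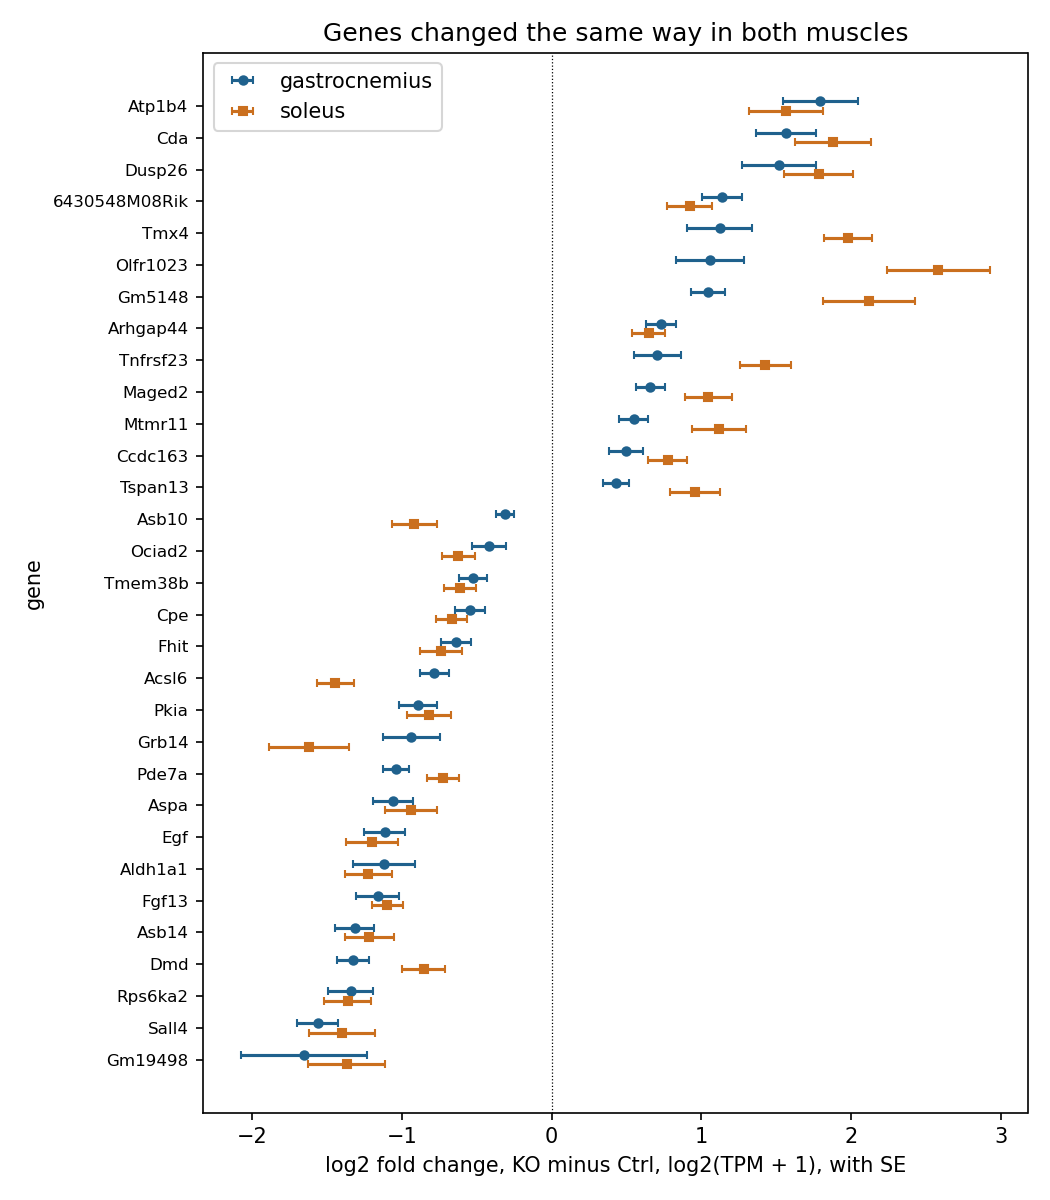
Log2 fold change (horizontal axis, KO minus Ctrl on log2(TPM + 1), with SE) in gastrocnemius (blue) and soleus (orange) of 31 gastrocnemius calls that also passed in soleus, in the same direction, when the soleus p-values were adjusted over the gastrocnemius calls alone, an alternative chosen after seeing the data. Atp1b4 is highest in gastrocnemius at 1.80, with 1.57 in soleus, and Dmd lies at -1.33 and -0.86.

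The change differed between muscles in 33 of 12091 genes, 19 with a soleus change above and 14 below that in gastrocnemius, and in 25 the signs were opposite. Cbfb, the partner subunit of RUNX transcription factors, fell in gastrocnemius from 66.3 ± 6.39 to 36.9 ± 7.41 TPM and was at 18.4 ± 0.630 and 26.5 ± 1.62 TPM in soleus Ctrl and KO (difference 1.35, SE 0.181, adjusted p = 0.0215). Ctxn3, a small cortexin membrane protein, rose in gastrocnemius from 24.5 ± 4.22 to 53.6 ± 12.5 TPM and was at 14.0 ± 0.570 and 8.05 ± 0.707 TPM in soleus (difference -1.82, SE 0.221, adjusted p = 0.0193). Klhdc1, a substrate receptor of a ubiquitin ligase, rose in gastrocnemius from 20.0 ± 0.541 to 56.9 ± 3.94 TPM and was at 15.1 ± 0.360 and 18.96 ± 3.18 TPM in soleus (difference -1.16, SE 0.151, adjusted p = 0.0193). The phosphate exporter Xpr1, the mitochondrial calcium uptake protein Micu3 and Vapb, a tether of the endoplasmic reticulum, fell in gastrocnemius and were 1.08, 0.86 and 0.75 higher in the soleus change.

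Cntnap2, which fell in gastrocnemius, was below the expression filter in soleus at 0.183 ± 0.0743 and 0.205 ± 0.0965 TPM (difference 1.69, SE 0.156). Tecrl, a reductase of the sarcoplasmic reticulum, was at 0.153 ± 0.0193 and 0.155 ± 0.0432 TPM in gastrocnemius and at 7.80 ± 0.858 and 2.93 ± 0.620 TPM in soleus (difference -1.17, SE 0.178). Hspa2, at 2.86 ± 0.582 and 2.17 ± 0.120 TPM in gastrocnemius, and the membrane metalloproteinase Mmp15, at 9.78 ± 0.200 and 12.4 ± 0.552 TPM there, differed by -1.27 and -0.76. The number of genes that differed ranged from 1 to 308 when a library was left out, and was 0 with the replicate number as a block (limma). Other settings moved it from 1, with the pseudogene covariate, to 292, with array weights.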

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

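The tests on the number of processed pseudogenes and on Gm12338 were chosen only after the library differences were seen, and the predictions for the correlation and the 5 list shares were written after their values.

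The 1704 gastrocnemius calls go together with a library property, the number of processed pseudogenes, that follows genotype in this muscle. Over protein-coding genes the gastrocnemius effect correlated with the soleus slope on that number within genotype at r = 0.323. That property predicts such a correlation, but the threshold for it was written after the value was seen. The slope includes soleus KO 3, which stood apart, and was not computed without it. The sign of the library shift was shared by 81.6% of the calls, against 65.5% of all genes. With the number as a covariate the slope of the effect on the uncorrected effect was 0.603, and after GC and length correction the number of calls was 79.6% of the main count (1356, of which 1121 are among the 1704), both undecided, so the property may account for part of the calls and a genotype effect for another part. The library shift was 0.0568 of the gastrocnemius median for developmental genes, 0.0440 for ribosomal proteins and -0.0841 for p53 targets. These shares are lower than that property predicts, but they argue only weakly against it for these lists. The shift has 1 library on one side in each genotype, includes soleus KO 3, which stood apart, and was not computed without KO 3. Shares of 0.0958 for neuromuscular junction and 0.370 for mitochondrially encoded genes leave that property open. The real split gave 1704 called genes and the highest other 3 (1 of 10 splits gave as many, too few for a share under 0.05), whereas all 10 of 10 splits gave at least the 5 lists called, up to 11, so the number of lists does not set the genotype split apart.

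The 31 genes changed in both muscles, including Dmd, Rps6ka2 and Asb14, were found by an adjustment chosen after both muscles had been seen. With the pseudogene number as a covariate the slope of corrected on uncorrected effects was 1.05 in gastrocnemius. Within genotype that number varied mostly in soleus (SD 345 and 240, against 72.7 and 122 in gastrocnemius). The 31 genes were chosen for a small soleus p, which favours little such spread, so this slope decides nothing about that number as a cause. After GC and length correction the slope was 0.979, which argues against GC and length bias as the whole cause of these fold changes. In soleus, where the pseudogene number hardly follows genotype, the covariate slope of 1.01 also decides nothing. In gastrocnemius the covariate ended most calls, with an SE 1.52 times as wide at the median. Splits were counted only for the 4 genes called in both over all genes, not for the 31. Of 100 splits with labels exchanged within muscles, the real one included, 1 gave at least 4, and the highest other gave 3. Every other gastrocnemius split called at most 3 genes, so a draw with gastrocnemius labels exchanged could not reach 4. The count therefore decides little about the overlap itself. The number of processed pseudogenes in gastrocnemius, the genotype, which the design gives, and any other difference between the mice, such as litter, which the labels do not give, stay open. Within the genotype, loss of Phf2 and the presence of Cre, which only KO mice carried, cannot be told apart.

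Soleus KO 3 stood apart, with a mean correlation to the other libraries of 0.968 (others 0.978 to 0.982), 39.0% mitochondrial transcripts and Myh7 at 1795 TPM (4055 to 5717 in the other soleus libraries). Its distance to the other soleus libraries was 1.41 times the largest of the others before and 1.22 times after GC and length correction, which leaves that explanation undecided. Against KO 1 and KO 2 the median of the fast fibre list was -0.70 and that of the slow fibre list -0.45. The rise of the fast list that another mix of fibre types predicts was thus not seen. TPM has a fixed sum, so the high mitochondrial share lowers nuclear genes, and the GC slope also acts on them. These medians therefore do not decide about the mix. Myh2 was at 2152 TPM in KO 3 (2699 and 2304 in KO 1 and KO 2), Myh1 at 727 (1204 and 1095) and Myh4 at 43.0 (122 and 272). No other biological explanation was tested for this library.

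The soleus calls numbered 9 in the real split and 9 in the split of Ctrl 1, Ctrl 3 and KO 2 against the rest, which is exactly the split by presence of Gm12338, so 2 of 10 splits gave at least as many, and with that class as a term limma called 0 genes (1080 at an unadjusted p under 0.05). Soleus lists numbered 13, with 4 of 10 splits giving at least as many and a highest other count of 20.

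The KO minus Ctrl change differed between the muscles, by a test of the difference itself, for 33 genes. The number of processed pseudogenes follows genotype in gastrocnemius and hardly in soleus, so this property enters the difference together with genotype. Of 100 splits, the real one included, 2 gave at least as many. Exchanged labels move genotype differences into the spread within groups, which lowers most other counts. The share therefore does not decide whether the effect depends on the muscle. The highest other count of 428 is many times the real number. It points to a structure of the samples, which may be the genotype groups themselves. The split that reverses the labels in soleus alone was open to the draw, keeps these groups and tests the sum of both KO effects. Which split gave 428 was not recorded, so the structure was not identified. By the rule for named genes the soleus effect minus the gastrocnemius effect was 1.69 for Cntnap2, 1.08 for Xpr1, 1.35 for Cbfb, 0.86 for Micu3 and 0.75 for Vapb. It was -1.82 for Ctxn3, -1.16 for Klhdc1, -1.17 for Tecrl, -0.76 for Mmp15 and -1.27 for Hspa2.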

How the results depend on the processing

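With 3 libraries per group, TPM without depth and a library property that follows genotype in gastrocnemius, the counts moved with many choices, and where a value moved the cause was not tested. The GC and length correction, protein-coding rescaling, pseudogene covariate, Gm12338 term and adjustment over gastrocnemius calls were chosen after seeing the data. Of the alternative values of called named genes other than leaving out a library, 1457 stayed called, 345 lost the call and 5 turned direction in gastrocnemius, 96 stayed and 39 lost it in soleus, and 96 stayed and 41 lost it for the difference. Leaving out a library, 485 stayed and 247 lost it in gastrocnemius, 5 and 48 in soleus, and 52 and 68 for the difference. Of the values of named genes not called as first fitted, 36 passed in gastrocnemius and 90 in soleus under other settings (Myh4 in gastrocnemius with quantile normalization, 0.38, adjusted p = 0.00919), and 8 and 5 when a library was left out. The residuals gave no sign that the replicate numbers pair the libraries, which 3 pairs cannot exclude: same-number residuals correlated at -0.157 to 0.0263 (gastrocnemius Ctrl with KO), -0.372 to -0.187 (soleus), -0.126 to 0.222 (Ctrl between muscles) and -0.157 to 0.0152 (KO between muscles), and a library was closest to its own number in 0, 0, 1 and 0 of 3 cases.

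Phf2 in gastrocnemius (main -0.41) passed the threshold with a filter at 5 TPM (-0.41), median-ratio scaling (-0.45), quantile normalization (-0.45), array weights (-0.44), GC and length correction (-0.47) and protein-coding rescaling (-0.49). It was -0.74 with the pseudogene covariate (adjusted p = 0.294). It ranged from -0.52 to -0.31 when a library was left out and passed without Ctrl 3 (-0.52, adjusted p = 0.0243). In soleus it ranged from -0.79 to -0.52 when a library was left out and passed in no setting.

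Counts are given as gastrocnemius higher and lower, soleus higher and lower, differing between muscles, and changed in both, from main values of 1110, 594, 2, 7, 33 and 4, where they moved over 1.5 times. Pseudocount 0.1 gave 1 soleus higher and 14 differing. No filter gave 342 gastrocnemius lower, 0 and 0 soleus (1738 at an unadjusted p under 0.05 by limma) and 0 in both. A filter at 5 TPM gave 1 soleus higher and 4 lower. Median-ratio scaling gave 21 differing, and quantile normalization 959 gastrocnemius lower and 21 differing. Rescaling without mitochondrial genes gave 8 soleus higher, 16 differing and 9 in both. Array weights gave 914 gastrocnemius lower, 5 and 14 soleus, 292 differing and 10 in both. The replicate block gave 491 and 231 gastrocnemius, 0 and 0 soleus (727 unadjusted), 0 differing and 0 in both. A fit of all libraries gave 259 and 265 gastrocnemius, 38 and 60 soleus and 42 in both. GC and length correction gave 390 gastrocnemius lower, 4 soleus higher and 7 differing. Protein-coding rescaling gave 703 and 918 gastrocnemius, 14 and 12 soleus, 19 differing and 16 in both. The pseudogene covariate was added to the fit of all libraries, whose counts and not the main ones are its baseline within each muscle. It gave 1 and 2 gastrocnemius, 43 and 59 soleus, 1 differing and 1 in both. The Gm12338 term gave 0 and 0 soleus (1080 unadjusted), and adjustment over gastrocnemius calls 13 and 19 soleus, of which 31 changed the same way in both. Leaving out a library, counts ranged over 382 to 960 and 165 to 636 in gastrocnemius, 0 to 6 and 0 to 5 in soleus, 1 to 308 differing (308 without soleus KO 2) and 0 to 9 in both.

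Lists (main 5 in gastrocnemius and 13 in soleus) numbered 3 in gastrocnemius with GC and length correction, 9 with the pseudogene covariate, 0 with an estimated correlation and 3 with fry. In soleus they numbered 7 with no filter, 8 with array weights, 7 in a fit of all libraries, 6 with the pseudogene covariate, and 0 with an estimated correlation and with fry. Leaving out a library they numbered 4 to 9 in gastrocnemius (9 without KO 3) and 5 to 12 in soleus (5 without Ctrl 2 and 8 without KO 1).

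With the pseudogene covariate, which moves with genotype in gastrocnemius and widens the SE there, gastrocnemius fold changes turned sign to 0.0242 for Ndufb5 gastrocnemius, -0.0836 for Hrc gastrocnemius, -0.11 for Canx gastrocnemius, -0.13 for Calr gastrocnemius, 0.0745 for Dnajb9 gastrocnemius, -0.23 for Dpt gastrocnemius, -0.47 for Mustn1 gastrocnemius, -0.31 for Myh7 gastrocnemius and -0.78 for Myh4 gastrocnemius. Leaving out a library, Myh7 gastrocnemius ranged from -0.24 (without KO 2) to 0.56.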

Other observations

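The soleus p-values were adjusted over the gastrocnemius calls only after both muscles had been seen, and the genes in this part were chosen after their values were seen. On that adjustment, 31 genes passed in soleus in the same direction as in gastrocnemius, 13 up and 18 down, and 1, Ctxn3, in the opposite direction. This list was chosen on these samples and is not independent evidence of its direction. Dmd, which encodes dystrophin, fell in gastrocnemius from 28.8 ± 0.450 to 10.9 ± 1.63 TPM and in soleus from 30.3 ± 1.41 to 16.5 ± 2.73 TPM. The ubiquitin ligase adaptors Asb14 and Asb10 fell by 1.32 and 0.31 in gastrocnemius and by 1.22 and 0.92 in soleus on the log2 scale. Egf, the epidermal growth factor, fell from 19.1 ± 2.56 to 8.29 ± 1.31 TPM in gastrocnemius and from 9.22 ± 0.258 to 3.53 ± 1.03 TPM in soleus. Aldh1a1, which makes retinoic acid, fell by 1.12 and 1.23 on the log2 scale, Grb14, an adaptor that inhibits the insulin receptor, by 0.94 and 1.62, and Sall4 by 1.56 and 1.40. Pkia, an inhibitor of protein kinase A, fell by 0.89 and 0.82, and the phosphodiesterase Pde7a, which breaks down cyclic AMP, by 1.04 and 0.73. Tmem38b, a potassium channel of the endoplasmic reticulum, fell by 0.53 and 0.61, and Cpe, carboxypeptidase E, by 0.55 and 0.67.

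Among the genes that rose in both muscles, Dusp26, a dual-specificity phosphatase, rose from 12.8 ± 4.96 to 36.9 ± 3.55 TPM in gastrocnemius and from 9.95 ± 1.92 to 37.6 ± 12.1 TPM in soleus. Cda, cytidine deaminase, rose by 1.57 and 1.88 on the log2 scale, Atp1b4 by 1.80 and 1.57, Maged2 by 0.66 and 1.04, and Tnfrsf23 by 0.70 and 1.43. Of the 31, 18 remained called in gastrocnemius when each library was left out in turn.

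Of 236 processed pseudogenes tested in gastrocnemius, 47 were higher and 12 lower in KO, against 1110 and 594 of all 11911 genes tested. In soleus 0 of 249 were called by limma, where 1102 genes of all kinds had an unadjusted p under 0.05.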
